A study of Danio rerio with 166 samples.

How the data were processed

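RNA was measured in 166 libraries of muscle, skin, heart, brain, eyes, intestine and gills from zebrafish of 3 genotypes (WT, KO and OE of atf3) at 2 and 4 months of age. Per the labels, the fish were killed with Tricaine, RNA was stored in NucleoProtect, purified with NucleoSpin RNA Clean-up and checked on a TapeStation, and libraries made with Illumina Stranded mRNA Prep were read in pairs on a NovaSeq X Plus. The submitters' processing notes name STAR, RSEM, DESeq2 and the GRCz11 assembly, with versions not given in the sources used here. The deposited table of expected counts holds fractional read counts per gene, per the file headers, and the deposited table of TPM holds transcript levels scaled to a fixed sum. Both hold 32057 genes. In the expected counts 4.32% of values were not whole and were rounded. The TPM of each library summed to 999998.75 to 1000001.17, and TPM were used only for this check. All columns were mapped to a tissue, genotype, age and replicate from their names and the labels, 0 being left over. Of the genes, 11229 had no symbol in the file, and 8201 of these were named from a reference table of another assembly, GRCz12tu.

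Each tissue was fitted alone with its 6 groups, in edgeR 4.0.16 under R 4.3.3. Genes with low counts were removed with edgeR's own filter, which left 12542 genes in muscle, 14258 in brain, 15075 in eyes, 15496 in gills, 15619 in heart, 12960 in intestine and 16385 in skin. Libraries were scaled by TMM, and a quasi-likelihood test gave each gene a log2 fold change and a p-value. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. KO and OE were compared with WT at each age, their effects were compared between ages as an interaction, and WT of 4 months was compared with WT of 2 months. The SE of a fold change was derived from its test. Levels are CPM on TMM-scaled library sizes.

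The comparisons, the alternatives not said to be later, the rule for naming genes and the lists of genes, 17 of pathways and 15 of markers of cell types, were written before the data were examined. The lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01 between genes of a list, for lists with at least 5 members tested. The counts of members adjusted over the list alone come from the same p-values adjusted among the members. The clock genes were divided into a dawn and a dusk arm after gene results had been seen and before the arms were computed. Genes named in the text were chosen by a rule: atf3; among genes past the threshold with an absolute log2 fold change of at least 1, a mean of at least 1 CPM and no overlap of libraries, up to 10 higher and 10 lower per muscle comparison and up to 2 each way elsewhere, by adjusted p; genes recurring in at least 4 tissues, up to 8; up to 4 called members of each list described; up to 2 genes per difference between ages; and for WT age up to 5 each way in muscle and 1 elsewhere.

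The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate number as a block as for paired samples, only the compared groups in the fit, each library left out in turn, and a correlation estimated for each list. Leaving out doubted libraries, the summed oocyte markers as a covariate in muscle and skin, and thinning of muscle to equal depth were added after the data had been seen. A library was doubted where its total was under 1000000 counts or where markers of another organ reached over 10000 CPM and over 5 times the median of its tissue. Doubted were 4 libraries of muscle, 2 of brain, 2 of eyes, 1 of gills, 1 of heart, 4 of intestine and 5 of skin. They were kept in the reported fit. By the correlation of their deviations, libraries of the same number paired in 2 of 35 comparisons, KO with WT intestine at 2 months (lowest r = 0.275) and WT age of brain (lowest r = 0.163). No pair among 246 pairs of replicates was identical. The fit was tested on simulated data with 200 changed genes, and edgeR found between 22 and 83 of each 100 at 4-fold, between 0 (muscle and skin) and 44 at 2-fold, and at most 6 false ones. For a difference between ages at 4-fold it found between 0 (muscle and skin) and 56. Other splits of the same libraries, 35 per comparison of 4 with 4 or 4 with 3 and 60 draws per difference between ages, were fitted in the same way.

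The depth per library, given in the report, varied by more than 100-fold, and a gene at 1 CPM in a library of 3080451 counts has about 3 reads.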

Results

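RNA was sequenced from 7 organs of zebrafish (Danio rerio) of 3 genotypes killed at 2 or 4 months of age. The genotypes were wild type (WT), a line deficient in atf3 made with CRISPR (KO) and a line overexpressing atf3 made with pTol2 (OE), a vector that places its insert in the genome by transposition. The atf3 gene (ENSDARG00000007823) encodes activating transcription factor 3, a stress-induced transcription factor of the ATF/CREB family. The title of the series names proliferation, muscle growth and ageing as its subject, so muscle is described first and in most detail. Brain, eyes, gills, heart, intestine, skeletal muscle and skin made 42 groups of 4 libraries each, except the WT gills and WT skin of 4 months, which had 3. The total count of a library ran from 167240 to 112796069, with a median of 3080451. In muscle it ran from 1141621 to 10419443, in heart from 1743833 to 90542873, in skin from 475351 to 112796069 and in intestine from 167240 to 24408438. Log2 fold changes below are given ± SE and levels as CPM, counts scaled to a library total ± SD, with n = 4 libraries per group unless stated. Adjusted p-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A gene is said to have risen or fallen where that adjusted p was under 0.05. The labels do not say that replicates are separate fish, so the p-values measure only the spread between libraries. The labels give no cohort or batch, so a difference between ages cannot be told from one between cohorts.

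The atf3 transcript was measured first in every group, as both lines were made to alter it. In muscle of 4 months it stood at 126 ± 100.1 CPM in OE against 3.05 ± 1.68 CPM in WT, a rise of 5.38 ± 1.04 (adjusted p = 0.0057), with the OE libraries between 69.5 and 276 CPM. In muscle of 2 months the OE libraries ran from 5.73 to 578 CPM (166 ± 275 CPM) against 7.78 ± 2.77 CPM in WT, and the difference of 4.40 ± 0.97 did not pass (adjusted p = 0.077). Outside muscle atf3 was not called in OE at either age, and the nearest to the threshold was heart at 4 months with 1.81 ± 0.64 (adjusted p = 0.13), at 34.8 ± 13.1 CPM in OE and 10.8 ± 12.4 CPM in WT. In KO of 2 months the estimate was below WT in all 7 tissues, from -0.61 ± 0.47 in brain to -2.44 ± 0.74 in skin (adjusted p = 0.29), and none passed. In KO of 4 months the estimates ran from -0.45 ± 0.78 in skin to 0.80 ± 0.66 in intestine, and again none passed. KO muscle held 3.16 ± 0.25 CPM at 2 months and 4.37 ± 3.25 CPM at 4 months. Where the edit lies in the gene is not given, so the transcript level does not check the loss of the protein.

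**Figure D1:**
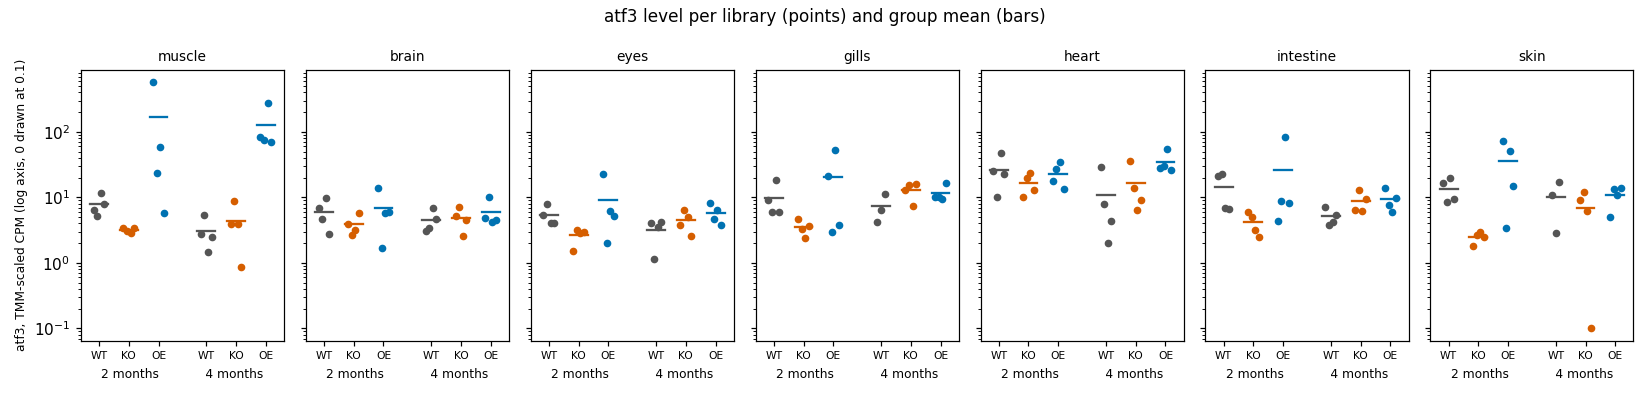
Level of atf3 (CPM, log axis, with 0 drawn at 0.1) by tissue, age and genotype, with 1 point per library and bars at group means. The 4 OE muscle libraries of 4 months lie between 69.5 and 276 CPM, above all WT and KO muscle libraries.

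The KO muscle of 2 months was compared with WT to ask what the loss of atf3 changes in the muscle of young adults. Of the few genes that passed, 4 were on the circadian clock list. The period genes per1b and per3, repressors in the core of the clock, fell by 2.03 ± 0.41 and 2.54 ± 0.46 (adjusted p = 0.047 and 0.020), and the clock repressor ciarta fell by 4.48 ± 0.66, from 11.7 ± 6.03 to 0.603 ± 0.801 CPM (adjusted p = 0.0061). The transcription factor gene nfil3-5, of a family that opposes the clock's activators, rose by 3.77 ± 0.56, from 4.04 ± 2.59 to 56.3 ± 27.9 CPM, and the cryptochrome gene cry3b, not on that list, rose by 1.98 ± 0.31 (adjusted p = 0.0061 for both). Of 32 circadian clock genes tested, 1 rose and 3 fell, and 6 were higher and 10 lower adjusted over the list alone, while the list as a whole was not called (adjusted p = 0.73). Among other genes, cyp24a1, which encodes the vitamin D 24-hydroxylase, rose by 5.58 ± 0.89 (adjusted p = 0.0068), and the gene of the heat shock factor hsf2 fell by 2.83 ± 0.55 (adjusted p = 0.042). Of 39 cell cycle genes, 1 fell, the spindle gene nusap1, by 4.95 ± 1.0 (adjusted p = 0.047), and 34 were lower adjusted over the list alone. The cell cycle list was called lower, with adjusted p = 0.73 with an estimated correlation. Markers of the oocyte moved with it: all 21 were lower adjusted over the list alone (0 among all genes, adjusted p = 0.83 with an estimated correlation), and their summed level was 13817 CPM in WT replicate 4 and 0.385 CPM or less in the 4 KO libraries. In all, 17 of 12542 genes passed, 5 higher and 12 lower. The count was 218 without WT replicate 3 and 4 without KO replicate 3, and it was 866 with DESeq2 and 0 with only the compared groups in the fit.

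The OE muscle of 2 months was compared with WT to ask what extra atf3 changes at that age. The Kruppel-like factor genes klf11b and klf9 rose by 3.82 ± 0.54 and 2.88 ± 0.42 (adjusted p = 0.0032 and 0.0035), the kelch gene KLHL38 rose by 4.45 ± 0.63 (adjusted p = 0.0032), and cebpd, of the C/EBP transcription factors, rose by 2.55 ± 0.42 from 35.8 ± 12.7 to 210 ± 21.5 CPM (adjusted p = 0.0070). Of 23 muscle atrophy genes 1 rose, trim63b, a muscle ubiquitin ligase that marks contractile proteins for breakdown, by 2.4 ± 0.43 (adjusted p = 0.016), and 2 were higher adjusted over the list alone. That list was called higher, with adjusted p = 0.39 with an estimated correlation. The gene irs2a rose by 2.44 ± 0.49 (adjusted p = 0.043), and sesn1, a sestrin induced by stress, by 2.22 ± 0.42 (adjusted p = 0.025). Genes that fell were odc1, which encodes the ornithine decarboxylase that starts polyamine synthesis, by 3.48 ± 0.57 (adjusted p = 0.0070), and XPO1, which encodes a nuclear export receptor, by 1.72 ± 0.32 (adjusted p = 0.022). The symbol XPO1 belongs to 2 genes of the file, and the one reported throughout is ENSDARG00000078041. Heat shock genes had a median of -0.52, with 0 of 36 called and 4 lower adjusted over the list alone, and the list was called lower (adjusted p = 0.37 with an estimated correlation). Hepatocyte markers were higher as a list, 15 of 21 adjusted over the list alone (0 among all genes, adjusted p = 0.84 with an estimated correlation). In all 18 genes passed, 16 higher and 2 lower. The count was 9 without WT replicate 1 and 0 with only the compared groups in the fit, and 140 without the doubted libraries described in the processing.

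At 4 months the KO muscle was compared with WT to ask what the loss of atf3 changes in older muscle. More genes rose than fell. The alanine aminotransferase genes gpt2 and GPT rose by 2.6 ± 0.38 and 3.51 ± 0.56 (adjusted p = 0.0041 and 0.0049), the latter from 9.73 ± 4.17 to 111 ± 89.9 CPM, and bbox1, of the last step of carnitine synthesis, rose by 2.66 ± 0.39 (adjusted p = 0.0041). KLHL38 rose by 3.45 ± 0.56 (adjusted p = 0.0049). Of 23 muscle atrophy genes 2 rose, trim63a by 2.84 ± 0.71 (adjusted p = 0.049) and the autophagy gene map1lc3a by 2.13 ± 0.47 (adjusted p = 0.027), and 9 were higher adjusted over the list alone. The list was called higher, with adjusted p = 0.37 with an estimated correlation. The immediate early gene csrnp1a rose by 2.43 ± 0.36 (adjusted p = 0.0041). Among genes that fell were tsr1 by 1.80 ± 0.29, pak1ip1 by 1.81 ± 0.30, gnl3, which encodes nucleostemin, by 1.4 ± 0.27 and the threonyl-tRNA synthetase gene tars1 by 1.28 ± 0.25 (adjusted p = 0.0049, 0.0051, 0.013 and 0.014). Of 36 heat shock genes, hspb6 rose by 2.43 ± 0.61 and hsp90aa1.1 fell by 2.02 ± 0.50 (adjusted p = 0.049 for both), 2 were higher and 8 lower adjusted over the list alone, and the list was called lower (adjusted p = 0.39 with an estimated correlation). In all 168 genes passed, 135 higher and 33 lower. The count was 28 without WT replicate 1, 549 without WT replicate 3, 325 without the doubted libraries, 314 with the oocyte covariate, 576 with DESeq2 and 0 with only the compared groups in the fit. WT replicate 2 held 15831 CPM of oocyte markers and WT replicate 3 held 34632 CPM of epidermis markers.

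The OE muscle of 4 months, in which atf3 itself rose, differed from WT in the most genes of any muscle comparison. More genes fell than rose. The spliceosome genes snrpe, snrpf and snrpg fell by 3.04 ± 0.45, 2.38 ± 0.36 and 2.52 ± 0.33 (adjusted p = 0.0015, 0.0015 and 0.00053), the ribosome assembly factor gene mrto4 by 2.33 ± 0.35 (adjusted p = 0.0015), and tars1 by 2.19 ± 0.25, from 45.7 ± 10.1 to 9.94 ± 0.71 CPM (adjusted p = 0.00023). Of 39 cell cycle genes 30 fell and 34 were lower adjusted over the list alone, with cdk1 lower by 3.88 ± 0.84 and ccna2 lower by 5.41 ± 1.32 (adjusted p = 0.011 and 0.015). The list was called lower, with adjusted p = 0.73 with an estimated correlation. Oocyte markers moved with these genes. Of 21, 20 fell (20 adjusted over the list alone), and their summed level was 35.2 to 15831 CPM in the WT libraries and 0.30 to 1.24 CPM in the OE libraries (adjusted p = 0.75 with an estimated correlation). All 7 vitellogenins, yolk precursors whose near-identical copies make single values uncertain, also fell (7 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation), from a sum of 30.8 to 8702 CPM to at most 1.2 CPM. Heat shock and folding genes fell more often than they rose, 14 against 3 of 36 (15 and 3 adjusted over the list alone), with the chaperone gene hspa5 lower by 2.81 ± 0.58 (adjusted p = 0.0081) and adjusted p = 0.56 with an estimated correlation for the list.

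Genes that rose in the same OE muscle of 4 months included 7 of 23 muscle atrophy genes (7 adjusted over the list alone), such as map1lc3a by 2.47 ± 0.47 and ulk1a, a kinase that starts autophagy, by 1.72 ± 0.47 (adjusted p = 0.0053 and 0.021). That list was called higher, with adjusted p = 0.39 with an estimated correlation. KLHL38 rose by 3.2 ± 0.55 and the deubiquitinase gene USP19 by 1.56 ± 0.24 (adjusted p = 0.0037 and 0.0017), and the selective autophagy receptor gene calcoco2 by 3.0 ± 0.46, from 27.4 ± 14.3 to 218 ± 51.0 CPM (adjusted p = 0.0015). Of 94 oxidative phosphorylation genes 11 rose and 3 fell (2 and 0 adjusted over the list alone), with ndufs8a of complex I higher by 1.68 ± 0.39 (adjusted p = 0.013) and adjusted p = 0.80 with an estimated correlation. Of 43 fast muscle genes 8 rose and 2 fell, the same numbers as adjusted over the list alone, with the parvalbumin gene pvalb4 higher by 1.80 ± 0.49 and the actin gene acta1b lower by 5.04 ± 1.03 (adjusted p = 0.022 and 0.0078). The whole list had adjusted p = 0.79 with an estimated correlation. Among 21 myogenic and growth regulators 3 rose (2 adjusted over the list alone), such as six1b by 1.6 ± 0.43 (adjusted p = 0.020), and the list was called higher (adjusted p = 0.77 with an estimated correlation). All 17 exocrine pancreas markers rose (17 adjusted over the list alone, adjusted p = 0.75 with an estimated correlation). Their sum reached 36064 CPM in OE replicate 2, against 266 CPM or less in WT. Of 15 erythrocyte markers 7 rose (11 adjusted over the list alone, adjusted p = 0.73 with an estimated correlation), among them alas2, of heme synthesis, by 2.91 ± 0.67 (adjusted p = 0.013). In all 2585 of 12542 genes passed, 870 higher and 1715 lower. The count was 312 without WT replicate 2, which held the most oocyte RNA, and 3724 without WT replicate 3. It was 2142 without doubted libraries and 95 with the oocyte covariate.

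**Figure D2:**
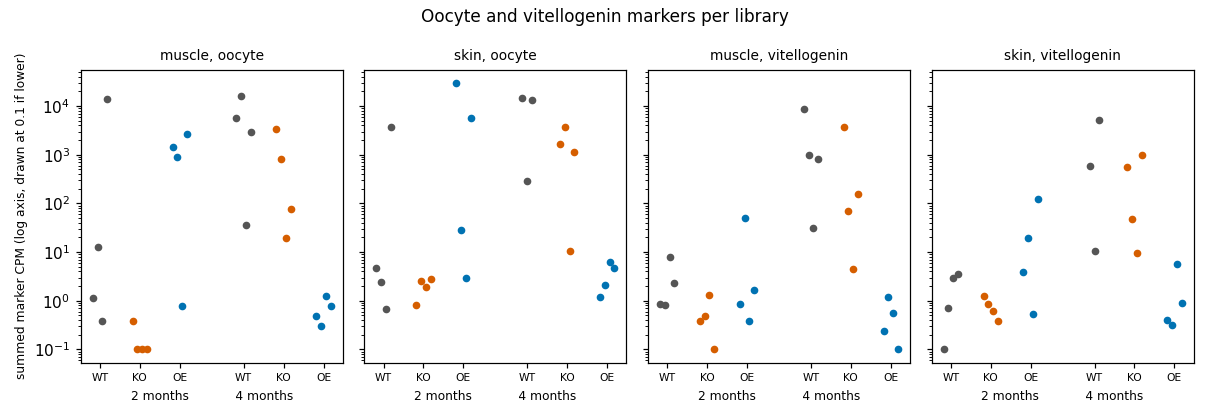
Summed level of oocyte markers (first pair of panels) and vitellogenins (last pair) in muscle and skin, in CPM (log axis, values under 0.1 drawn there), by age and genotype, with 1 point per library. For oocyte markers at 4 months the 4 OE muscle libraries lie between 0.30 and 1.24 CPM and the 4 WT muscle libraries between 35.2 and 15831 CPM.

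In the brain of KO fish of 2 months, cry3b and nfil3-5 rose by 1.74 ± 0.13 and 2.12 ± 0.22, and nr1d2b, a nuclear receptor that represses the clock's activators, and per1b fell by 1.77 ± 0.14 and 1.97 ± 0.21 (adjusted p = 1.7e-08 for cry3b and nr1d2b, 4.8e-06 for nfil3-5 and per1b). Of 36 clock genes 4 rose and 10 fell (12 and 14 adjusted over the list alone), and the list was not called (adjusted p = 0.12). Sterol synthesis genes rose, 3 of 29 with 12 adjusted over the list alone, hmgcs1 by 1.21 ± 0.23 and cyp51 by 0.99 ± 0.19 (adjusted p = 0.012 for both). As a list they had adjusted p = 0.37 with an estimated correlation. Among 38 cell cycle genes 1 fell, the replication helicase gene mcm5, by 1.4 ± 0.29 (adjusted p = 0.021), with 22 lower adjusted over the list alone and adjusted p = 0.39 with an estimated correlation. In all 54 of 14258 genes passed, 15 higher and 39 lower. At 4 months 14 genes passed, 10 higher and 4 lower, with the alanine aminotransferase gene gpt higher by 1.31 ± 0.18 and the nuclear RNA genes malat1 and rn7sk lower by 3.09 ± 0.42 and 2.49 ± 0.40 (adjusted p = 0.00081, 0.00081 and 0.0044). Immediate early genes had a median of -0.41 at 4 months, with 0 of 34 called and 4 lower adjusted over the list alone, and the list was called lower (adjusted p = 0.68 with an estimated correlation). The 2 month count was 28 without KO replicate 3, and the 4 month count was 42 without WT replicate 3, whose fast muscle markers summed to 18666 CPM.

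In the brain of OE fish of 2 months 1 gene passed, odc1, which fell by 1.18 ± 0.18 from 121 ± 35.0 to 53.4 ± 5.49 CPM (adjusted p = 0.020), and in all but 1 omission of a library it no longer did. At 4 months 6 genes passed, 1 higher and 5 lower. The small nuclear RNA gene rn7sk fell by 2.28 ± 0.38 and the vitellogenin gene vtg1 fell by 8.12 ± 1.31 (adjusted p = 0.028 for both), vtg1 from 121 ± 121 to 0.402 ± 0.606 CPM. Ribosomal protein genes had a median of -0.61 (0 of 83 called, 27 lower adjusted over the list alone) and cell cycle genes a median of -0.48 (0 of 38 called, 2 lower adjusted over the list alone). Both lists were called lower, with adjusted p = 0.75 and 0.73 with an estimated correlation. The 4 month count was 0 without OE replicate 2, 151 without WT replicate 2 and 92 with DESeq2, and with RLE scaling 2 genes were higher and 5 lower. The 92 genes of DESeq2 were 53 higher and 39 lower.

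In the eyes of KO fish of 2 months clock genes changed in both directions. The nuclear receptor gene nr1d1, a repressor of the clock's activators, fell by 5.96 ± 0.25, from 159 ± 20.7 to 2.34 ± 1.17 CPM, per1b fell by 3.08 ± 0.18, and nfil3-5 rose by 4.11 ± 0.26 (adjusted p = 1.9e-14, 2.7e-11 and 1.0e-10). Of 36 clock genes 7 rose and 14 fell (13 and 14 adjusted over the list alone), and the list was called lower, with adjusted p = 0.67 with an estimated correlation. Photoreceptor genes rose more often than they fell, 15 against 4 of 30 (19 and 5 adjusted over the list alone), and the list was called higher (adjusted p = 0.68 with an estimated correlation). The red cone opsin genes opn1lw1 and opn1lw2 rose by 2.09 ± 0.28 and 2.08 ± 0.28, though reads of these near-identical copies could be split wrongly, while the arrestin genes sagb and arr3a fell by 1.59 ± 0.20 and 1.43 ± 0.20 (adjusted p = 3.4e-05, 3.7e-05, 1.0e-05 and 4.3e-05). Of 26 lens genes 6 fell (7 adjusted over the list alone, adjusted p = 0.78 with an estimated correlation), among them the gamma crystallin gene crygm2d10 by 4.33 ± 0.45 (adjusted p = 7.5e-07), also 1 of several similar copies. Cell cycle genes fell, 13 of 36 (1 higher and 25 lower adjusted over the list alone, adjusted p = 0.39 with an estimated correlation), with tpx2 lower by 1.67 ± 0.27 (adjusted p = 0.00036). The p53 targets fell too, 5 of 27 (7 adjusted over the list alone, adjusted p = 0.73 with an estimated correlation), with the DNA repair gene ddb2 lower by 2.43 ± 0.25 (adjusted p = 4.9e-07). Markers of liver and pancreas moved with these groups, 9 of 11 and 7 of 7 lower (10 and 7 adjusted over the list alone, adjusted p = 0.73 and 0.79 with an estimated correlation). WT replicate 2 held 26105 CPM of hepatocyte and 8576 CPM of pancreas markers. In all 759 of 15075 genes passed, 277 higher and 482 lower, 1487 without WT replicate 3, 297 without KO replicate 3 and 415 without the doubted libraries, among them WT replicate 2.

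At 4 months the KO eyes showed 164 genes past the threshold, 103 higher and 61 lower. Cell cycle genes fell, 5 of 36 with 18 adjusted over the list alone, among them mki67, a marker of dividing cells, by 1.29 ± 0.29 and rrm2 by 1.88 ± 0.36 (adjusted p = 0.033 and 0.014). Together these genes had adjusted p = 0.37 with an estimated correlation. Of 36 clock genes 5 rose and 1 fell (10 and 1 adjusted over the list alone), with the bHLH repressor gene bhlhe41 higher by 1.0 ± 0.16 and nr1d4a by 1.21 ± 0.23 (adjusted p = 0.0049 and 0.014). Taken as a list, the genes had adjusted p = 0.75 with an estimated correlation. The chemokine gene ccl25b rose by 2.00 ± 0.28, and the blue cone opsin gene opn1sw2 fell by 1.04 ± 0.21 (adjusted p = 0.0023 and 0.015). The count was 34 without WT replicate 4 and 358 with DESeq2.

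In the eyes of OE fish of 2 months edgeR called 0 genes, with 2163 at an unadjusted p under 0.05 and 106 by DESeq2. Sterol and lipid synthesis genes had a median of -1.15, with 18 of 29 lower adjusted over the list alone, and heat shock genes a median of -0.40, with 10 of 35. Both lists were called lower, with adjusted p = 0.61 and 0.55 with an estimated correlation. Without WT replicate 3 the count was 617. At 4 months 13 genes passed, 7 higher and 6 lower. The sterol 12-alpha-hydroxylase gene cyp8b1.3 rose by 4.67 ± 0.62 and coch by 1.59 ± 0.26, while guca1g, a guanylate cyclase activator of photoreceptors, fell by 2.55 ± 0.47 (adjusted p = 0.0013, 0.019 and 0.037). Cell cycle genes had a median of -0.83 (0 of 36 called, 14 lower adjusted over the list alone) and fast muscle genes a median of 0.79 (0 of 41 called, 15 higher adjusted over the list alone), both lists being called, with adjusted p = 0.38 and 0.78 with an estimated correlation. The 4 month count was 1 without OE replicate 1 and 227 with only the compared groups in the fit.

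In the gills of KO fish of 2 months, nr1d1 and ciarta fell by 4.57 ± 0.33 and 3.8 ± 0.32, and nfil3-5 and rorcb, of a nuclear receptor family that activates clock genes, rose by 3.69 ± 0.26 and 3.85 ± 0.47 (adjusted p = 1.2e-08, 2.4e-07, 8.9e-09 and 4.4e-05). Of 36 clock genes 7 rose and 13 fell (10 and 13 adjusted over the list alone), and the list was called lower (adjusted p = 0.75 with an estimated correlation). Heat shock genes fell, 11 of 37 (1 higher and 13 lower adjusted over the list alone), with hsp70.2 lower by 2.46 ± 0.45 and hsp90aa1.2 by 1.95 ± 0.38 (adjusted p = 0.0025 and 0.0050). The list as a whole had adjusted p = 0.68 with an estimated correlation. Of 35 integrated stress response genes 4 fell (10 adjusted over the list alone), the glutathione-degrading enzyme gene chac1 by 1.55 ± 0.27 and atf4b by 0.74 ± 0.16 (adjusted p = 0.0015 and 0.0083). As a set the genes had adjusted p = 0.37 with an estimated correlation. Of 29 interferon response genes 6 rose (10 adjusted over the list alone), irf1b by 1.31 ± 0.25 and stat1a by 0.50 ± 0.12 (adjusted p = 0.0042 and 0.022). The whole list had adjusted p = 0.37 with an estimated correlation. Ionocyte markers rose, 4 of 21 (10 adjusted over the list alone), with the sodium pump gene atp1a1a.5 higher by 2.53 ± 0.68 (adjusted p = 0.036). As a list they had adjusted p = 0.73 with an estimated correlation. Hepatocyte markers fell, 11 of 13 (12 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation), against a sum of 6067 CPM in WT replicate 4 and 916 CPM or less in KO. In all 666 of 15496 genes passed, 300 higher and 366 lower, and 355 without WT replicate 4. At 4 months 171 passed, 58 higher and 113 lower, with 6 of 39 cell cycle genes lower (27 adjusted over the list alone), such as mki67 by 1.44 ± 0.31 (adjusted p = 0.029). Together these genes had adjusted p = 0.39 with an estimated correlation. The chemokine gene ccl19a.2 fell by 3.13 ± 0.41 and the lipoxygenase gene alox5b.2 by 3.08 ± 0.47 at that age (adjusted p = 0.0012 and 0.0058). The 4 month count was 14 without WT replicate 4 and 412 without WT replicate 3.

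The gills of OE fish of 2 months differed from WT in 1742 genes, 665 higher and 1077 lower. Their atf3 ran from 2.92 to 53.4 CPM, against 5.98 to 18.6 CPM in WT. Folding and heat shock genes fell, 23 of 37 (26 adjusted over the list alone), among them hspa5 by 2.3 ± 0.25, from 979 ± 120.2 to 199 ± 26.4 CPM and dnajb11 by 1.96 ± 0.20 (adjusted p = 5.7e-06 and 3.4e-06). Taken as a list, the genes had adjusted p = 0.37 with an estimated correlation. The translation factor gene eif4e1c fell by 2.24 ± 0.18 and pprc1, a coactivator of mitochondrial gene expression, by 2.42 ± 0.19 (adjusted p = 1.5e-07 for both). Sterol synthesis genes fell, 10 of 27 (13 adjusted over the list alone), ldlrb by 2.00 ± 0.29 (adjusted p = 0.00012). The list as a whole had adjusted p = 0.68 with an estimated correlation. Of 25 muscle atrophy genes 4 rose (6 adjusted over the list alone), with the autophagy kinase gene ulk1a higher by 1.62 ± 0.21 (adjusted p = 3.7e-05). The whole list had adjusted p = 0.37 with an estimated correlation. Clock genes rose, 12 of 36 against 1 that fell (20 and 1 adjusted over the list alone, adjusted p = 0.39 with an estimated correlation), with the bZIP activator gene dbpb higher by 1.23 ± 0.23 (adjusted p = 0.00099). Hepatocyte markers fell as in KO, 9 of 13 (10 adjusted over the list alone, adjusted p = 0.75 with an estimated correlation). Without WT replicate 4 the count was 1053. At 4 months 104 genes passed, 39 higher and 65 lower, with the matrix protein gene spp1 higher by 2.2 ± 0.32 and the triglyceride synthesis gene dgat2 lower by 4.58 ± 0.75 (adjusted p = 0.0046 and 0.010). Exocrine pancreas markers were lower at 4 months, 1 of 16 called and 16 adjusted over the list alone (adjusted p = 0.68 with an estimated correlation), at 127 to 1027 CPM in WT and 9.19 to 101 CPM in OE. The 4 month count was 13 without OE replicate 1 and 423 without WT replicate 3.

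In the heart of KO fish of 2 months, ciarta and per1b fell by 4.23 ± 0.33 and 2.63 ± 0.21, and rorcb and the tubulin gene tuba8l3 rose by 4.40 ± 0.50 and 1.98 ± 0.22 (adjusted p = 9.3e-08, 1.1e-07, 2.0e-05 and 1.9e-05). Of 35 clock genes 5 rose and 12 fell (9 and 15 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). Cell cycle genes fell, 6 of 41 (29 adjusted over the list alone), such as rrm2 by 1.96 ± 0.47 and kif11 by 2.14 ± 0.52 (adjusted p = 0.029 and 0.033). As a list they had adjusted p = 0.37 with an estimated correlation. Of 36 collagen and matrix genes 4 fell (12 adjusted over the list alone), col1a2 by 2.36 ± 0.60 (adjusted p = 0.040). Together these genes had adjusted p = 0.75 with an estimated correlation. Epidermis markers moved with them, 4 of 26 lower (1 higher and 20 lower adjusted over the list alone, adjusted p = 0.78 with an estimated correlation), and their sum was 69726 CPM in WT replicate 4 and 6650 CPM or less in KO. In all 370 of 15619 genes passed, 138 higher and 232 lower, 108 without KO replicate 3 and 648 without WT replicate 2. At 4 months 715 genes passed, 546 higher and 169 lower with the main scaling and 382 higher and 242 lower with RLE scaling. The ubiquitin conjugating enzyme gene ube2al rose by 1.90 ± 0.19, the autophagy receptor gene bnip3lb by 1.37 ± 0.23 and ctsla, which encodes cathepsin L, by 1.06 ± 0.21 (adjusted p = 9.2e-06, 0.0020 and 0.0064), the last pair among 7 of 25 atrophy genes that rose (7 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). The troponin gene tnni1c fell by 2.94 ± 0.42 (adjusted p = 0.00064). Erythrocyte markers rose, 10 of 17 (15 adjusted over the list alone, adjusted p = 0.62 with an estimated correlation), with the anion exchanger gene slc4a1a higher by 2.55 ± 0.50 (adjusted p = 0.0054), and summed to 30731 to 91726 CPM in KO against 6802 to 16072 CPM in WT. Without KO replicate 4 the 4 month count was 293, and without the doubted library of heart, WT replicate 4 of 2 months, it was 1509.

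In the heart of OE fish of 2 months 114 genes passed, 52 higher and 62 lower. Here irs2a rose by 3.43 ± 0.43 and fbxo32, a ubiquitin ligase of muscle atrophy and 1 of 25 genes of that list to rise (1 adjusted over the list alone), by 2.88 ± 0.44 (adjusted p = 0.00037 and 0.0021). Taken as a list, the genes had adjusted p = 0.53 with an estimated correlation. The shear-stress induced factor genes klf2a and klf2b, both immediate early genes of the list, fell by 1.78 ± 0.28 and 2.80 ± 0.48 (adjusted p = 0.0025 and 0.0041), the 2 called of 34 (2 higher and 6 lower adjusted over the list alone, adjusted p = 0.79 with an estimated correlation). Of 35 clock genes 4 rose (4 higher and 1 lower adjusted over the list alone), such as bhlhe41 by 1.41 ± 0.23 (adjusted p = 0.0029). The list as a whole had adjusted p = 0.73 with an estimated correlation. At 4 months 405 passed, 268 higher and 137 lower with the main scaling and 176 higher and 194 lower with RLE scaling. Cell cycle genes fell at that age, 6 of 41 (22 adjusted over the list alone), among them the polymerase clamp gene pcna by 1.3 ± 0.31 (adjusted p = 0.026). As a set the genes had adjusted p = 0.39 with an estimated correlation. The growth factor gene pdgfbb rose by 3.11 ± 0.43, and calua, of the secretory pathway, fell by 1.67 ± 0.22 (adjusted p = 0.0014 for both). Erythrocyte markers rose, 4 of 17 (15 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation), and summed to 21975 to 36761 CPM. The counts were 46 without OE replicate 2 at 2 months and 135 without WT replicate 2 at 4 months.

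In the intestine of KO fish of 2 months 11 of 38 cell cycle genes rose (14 higher and 1 lower adjusted over the list alone), with pcna higher by 1.90 ± 0.33 and mcm3 by 2.16 ± 0.40 (adjusted p = 0.0013 and 0.0025). The whole list had adjusted p = 0.77 with an estimated correlation. Of 30 immediate early genes 9 fell (1 higher and 13 lower adjusted over the list alone), with fosl1a lower by 4.76 ± 0.61 and junba by 2.03 ± 0.29 (adjusted p = 0.00015 and 0.00037). As a list they had adjusted p = 0.37 with an estimated correlation. Of 26 p53 targets 7 fell (7 adjusted over the list alone), with the cell cycle inhibitor gene cdkn1a lower by 3.76 ± 0.73 and ddb2 by 2.18 ± 0.27 (adjusted p = 0.0033 and 0.00014). Together these genes had adjusted p = 0.37 with an estimated correlation. Of 35 clock genes 2 rose and 12 fell (3 and 15 adjusted over the list alone, adjusted p = 0.55 with an estimated correlation). In all 1059 of 12960 genes passed, 512 higher and 547 lower, and 476 without WT replicate 2. At 4 months 35 passed, 11 higher and 24 lower, among them acbd4, which encodes an acyl-CoA binding protein, lower by 4.37 ± 0.70, and nr1d4b higher by 3.74 ± 0.63 (adjusted p = 0.014 and 0.019). Oxidative phosphorylation genes had a median of -0.76 at that age, with 0 of 92 called and 66 lower adjusted over the list alone, and the list was called lower (adjusted p = 0.55 with an estimated correlation). Exocrine pancreas markers had a median of 2.71 (0 of 24 called, 21 higher adjusted over the list alone, adjusted p = 0.77 with an estimated correlation). The 4 month count was 0 without KO replicate 2, 178 without WT replicate 3 and 712 with DESeq2.

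In the intestine of OE fish of 2 months atf3 ran from 4.35 to 83.2 CPM (6.55 to 22.4 CPM in WT). Of 29 heat shock and folding genes 15 fell (16 adjusted over the list alone), with hspa5 lower by 3.17 ± 0.34, from 1364 ± 234 to 151 ± 27.2 CPM, and dnajb9b at -4.02 ± 0.50 (adjusted p = 8.9e-06 and 3.5e-05). Taken as a list, the genes had adjusted p = 0.37 with an estimated correlation. Of 29 sterol and lipid synthesis genes 7 fell (9 adjusted over the list alone), with hmgcs1, which encodes HMG-CoA synthase, at -4.12 ± 0.68 (adjusted p = 0.00040). The list as a whole had adjusted p = 0.75 with an estimated correlation. The autophagy kinase genes ULK2 and ulk1a rose by 4.28 ± 0.33 and 5.12 ± 0.54, and fbxo32 rose by 4.84 ± 0.85 (adjusted p = 1.7e-07, 5.9e-06 and 0.00069), the last pair being part of 3 atrophy genes of 20 that rose (3 adjusted over the list alone, adjusted p = 0.37 with an estimated correlation). The stress granule gene g3bp1 fell by 3.25 ± 0.27, odc1 by 4.72 ± 0.47 and XPO1 by 3.29 ± 0.31 (adjusted p = 5.9e-07, 4.2e-06 and 2.4e-06). In all 1237 genes passed, 485 higher and 752 lower, and 788 without the doubted libraries, among them OE replicates 2 and 3 of this age. At 4 months 133 passed, 72 higher and 61 lower, and with RLE scaling 86 were higher and 107 lower. The amino acid transporter gene slc7a3a rose by 3.30 ± 0.50 and the cyclin gene ccnd1 by 1.86 ± 0.28, and acbd4 fell by 4.85 ± 0.69 (adjusted p = 0.0043, 0.0043 and 0.0042). Of 92 oxidative phosphorylation genes 4 fell (49 adjusted over the list alone), such as uqcr10 by 2.06 ± 0.38 (adjusted p = 0.016). As a set the genes had adjusted p = 0.62 with an estimated correlation. Vitellogenins fell, 4 of 7 (7 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation), from a sum of 3.39 to 158152 CPM in WT to between 1.44 and 2.34 CPM in OE. The 4 month count was 26 without OE replicate 4 and 1021 with DESeq2.

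In the skin of KO fish of 2 months 10 of 16385 genes passed, 1 higher and 9 lower, and clock genes were again among them. Here nr1d1 fell by 4.89 ± 0.67 and the DASH cryptochrome gene cry-dash by 2.39 ± 0.36, and trim35-14 rose by 3.92 ± 0.71 (adjusted p = 0.0062, 0.0093 and 0.042). Of 36 clock genes 3 fell (2 higher and 10 lower adjusted over the list alone, adjusted p = 0.79 with an estimated correlation). Interferon response genes had a median of 0.98, with 0 of 32 called and 10 higher adjusted over the list alone, and the list was called higher (adjusted p = 0.38 with an estimated correlation). Without KO replicate 1 the count was 0, and with DESeq2 it was 346. At 4 months edgeR called 0 genes, with 3111 at an unadjusted p under 0.05 and 410 by DESeq2. Atrophy genes had a median of 0.81 there (0 of 25 called, 9 higher adjusted over the list alone) and cell cycle genes a median of -2.04 (0 of 40 called, 7 lower adjusted over the list alone), both lists being called, with adjusted p = 0.37 and 0.75 with an estimated correlation. Here WT replicates 2 and 4 held 14761 and 13091 CPM of oocyte markers, and KO replicates 2 and 4 had 841857 and 475351 counts.

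In the skin of OE fish of 2 months edgeR called 0 genes, with 2267 at an unadjusted p under 0.05 and 138 by DESeq2. At 4 months 1749 passed, 216 higher and 1533 lower, in the comparison of 4 OE with 3 WT libraries. Cell cycle genes fell, 26 of 40 (1 higher and 36 lower adjusted over the list alone), among them aurkb, a mitotic kinase, by 3.84 ± 1.01 and mcm4 by 2.58 ± 0.73 (adjusted p = 0.041 for both). The whole list had adjusted p = 0.73 with an estimated correlation. Folding genes fell, 6 of 36 (9 adjusted over the list alone), with hspa5 lower by 2.57 ± 0.68 (adjusted p = 0.041). As a list they had adjusted p = 0.78 with an estimated correlation. The macrophage gene mpeg1.3 fell by 7.54 ± 1.09, from 24.2 ± 4.69 to 0.109 ± 0.126 CPM, and the nuclear receptor gene rorab rose by 1.68 ± 0.48 (adjusted p = 0.014 and 0.041). Oocyte markers fell with them, 19 of 21 (21 adjusted over the list alone, adjusted p = 0.73 with an estimated correlation), from a sum of 292 to 14761 CPM in WT to between 1.18 and 6.12 CPM in OE, and so did all 7 vitellogenins (7 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). The count was 0 without OE replicate 1, 3284 without WT replicate 3, and 0 with the oocyte markers as a covariate.

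**Figure D3:**
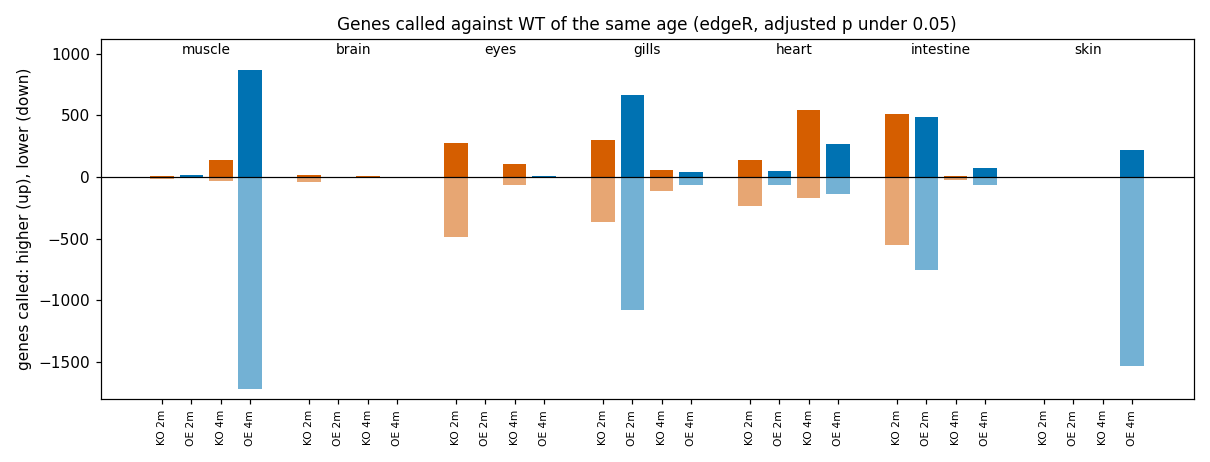
Number of genes past the threshold in each comparison of KO or OE with WT, by tissue and age, with higher genes above 0 and lower genes below. The most calls were the 2585 of OE muscle at 4 months, and OE eyes at 2 months, OE skin at 2 months and KO skin at 4 months had 0.

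Genes called the same way in several tissues were counted. In KO of 2 months 71 genes were called the same way in at least 3 tissues and 40 in at least 4. Lower in all 7 tissues were ciarta, per1b and cry-dash. In 6 tissues nr1d1, per3 and si:ch211-132b12.7 were lower and nfil3-5 was higher, and gstk1, a glutathione transferase gene, was lower in 5. In OE of 2 months 65 genes recurred in at least 3 tissues and 5 in at least 4. These were odc1 and XPO1, lower (as in KO of 2 months, in 5 and 3 tissues), and irs2a, klf11b and sesn1, higher. In KO of 4 months 14 recurred in at least 3 tissues and 3 in at least 4. The clock activator gene tefa was higher, by 0.85 ± 0.14 in brain and 1.01 ± 0.21 in heart (adjusted p = 0.0044 and 0.0089), as was the ubiquitin conjugating enzyme gene ube2q2, and malat1 was lower. In OE of 4 months 68 recurred in at least 3 tissues and 4 in at least 4. These were the histone methyltransferase gene ezh1 and the ubiquitin-like gene ubl3a, both higher, and vtg1 and acbd4, both lower. In KO acbd4 was also lower, at both ages.

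The clock list was divided by the time of day its genes peak into a dawn arm (such as per1b, nr1d1 and ciarta) and a dusk arm (such as nfil3-5 and bmal genes). In KO of 2 months the dawn median was below 0 in all 7 tissues, from -2.03 in muscle to -0.94 in skin. The dusk median was above 0, from 0.38 in muscle to 1.45 in heart. In eyes 11 of 16 dawn genes fell and 7 of 10 dusk genes rose, and in gills 10 fell and 5 rose. At 4 months only KO intestine had that orientation by sign (dawn -0.05, dusk 0.36), with 2 dawn genes higher and 0 lower. Brain, eyes, heart and muscle had the opposite (dawn 0.17, 0.50, 0.54 and 0.43, dusk -0.35, -0.09, -0.14 and -0.79).

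**Figure D4:**
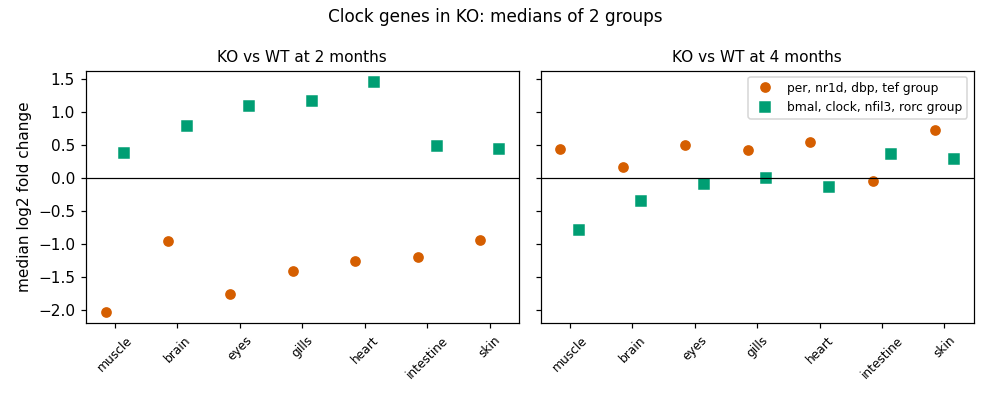
Median log2 fold change of the dawn and dusk genes of the clock (y axis) by tissue, for KO against WT at 2 and 4 months, with 1 point per arm. At 2 months every dawn median lies below 0 and every dusk median above 0.

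KO and OE shared their WT libraries, so their overlap was set beside what shared controls give. Simulated unchanged groups shared 0, having nothing to call. Separate controls split the WT libraries, which alone can lower the count. In gills of 2 months 92 genes were higher and 157 lower in both lines and 13 went opposite ways. Independent lists would share 12.9 and 25.4, and separate controls shared 51. The covariance of the fold changes was 0.308 against 0.106 simulated (r = 0.547 against 0.542), and with separate controls it was 0.127 (r = 0.192). In intestine of 2 months 41 were higher and 95 lower in both and 76 went opposite ways (19.2 and 31.7 for independent lists, 0 simulated, 38.3 with separate controls), and the covariance of 0.0958 was below the simulated 0.218 (r = 0.106 against 0.467) and was -0.171 with separate controls (r = -0.110). In heart of 4 months 128 were higher and 28 lower in both and 0 opposite (9.37 and 1.48 for independent lists, 0 simulated, 13.2 with separate controls), with a covariance of 0.997 against 0.574 (r = 0.665 against 0.729), and 0.116 with separate controls (r = 0.0447). In muscle of 4 months 87 were higher and 24 lower in both and 0 opposite (9.36 and 4.51, 0 simulated, 3.67 with separate controls), with a covariance of 1.22 against 0.275 (r = 0.694 against 0.492), and 0.847 with separate controls (r = 0.387).

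Whether a line's effect differed between ages was tested as the effect at 4 months minus that at 2 months. For KO 20 genes passed in muscle, 38 in brain, 199 in eyes, 444 in gills, 252 in heart, 544 in intestine and 2 in skin. In eyes the difference was 6.31 ± 0.30 for nr1d1 and 3.65 ± 0.24 for per1b, and in brain it was -3.11 ± 0.31 for nfil3-5 (adjusted p = 7.0e-13, 4.2e-10 and 4.0e-06). For OE 8 passed in muscle, 4 in eyes, 640 in gills, 88 in heart, 1474 in intestine and 3258 in skin. In brain edgeR called 0, with 800 at an unadjusted p under 0.05 and 4 by DESeq2. In intestine ULK2 had a difference of -5.10 ± 0.43 and g3bp1 of 4.22 ± 0.37, and in muscle mrto4 and tsr1 of -2.95 ± 0.49 and -2.27 ± 0.40 (adjusted p = 9.6e-07, 1.1e-06, 0.029 and 0.029). With RLE scaling the KO calls in heart moved from 200 higher and 52 lower to 165 and 79, the OE calls there from 67 and 21 to 36 and 27, and the OE calls in muscle from 1 and 7 to 4 and 6. The OE count in muscle was 2702 without WT replicate 4 of 2 months and 0 without OE replicate 2 of 2 months. That in skin was 786 without WT replicate 4 of 4 months, and 0 with the oocyte covariate, without the doubted libraries or with only the compared groups in the fit. Oocyte markers stood at 29905 CPM in OE skin replicate 1 of 2 months.

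WT fish of 4 months were compared with WT fish of 2 months as the background of age and cohort. In muscle 32 genes passed, 15 higher and 17 lower. Here cyp24a1, klf9 and the ubiquitin gene ubb were higher by 6.75 ± 0.87, 2.71 ± 0.42 and 3.14 ± 0.51, and serpinh1b, which encodes the collagen chaperone Hsp47, was lower by 5.87 ± 0.97 (adjusted p = 0.0014, 0.011, 0.013 and 0.013). The count was 1 without WT replicate 1 of 2 months, 1409 without WT replicate 4 of 2 months and 0 with only the compared groups in the fit. In brain 868 passed, in eyes 1414, in gills 2700, in heart 2019, in intestine 2503 and in skin 3. With only the compared groups in the fit these were 134, 208, 1342, 179, 1179 and 5. The clock gene nr1d4b rose by 5.91 ± 0.33 in eyes and 3.64 ± 0.29 in brain (adjusted p = 2.4e-11 and 6.5e-08), and serpinh1b fell by 6.49 ± 0.96 in skin (adjusted p = 0.019). Cell cycle genes were lower in brain, 15 of 38 (23 adjusted over the list alone), eyes, 9 of 36 (21), and heart, 11 of 41 (19), went both ways in gills (5 higher and 8 lower of 39), and were higher in intestine, 29 of 38 with 1 lower. In heart 27 of 42 fast muscle genes were lower (3 higher), as were 15 of 23 exocrine pancreas, 13 of 19 enterocyte and 12 of 21 lens markers, with medians of -5.73, -7.32, -6.59 and -3.55. In eyes 7 of 11 hepatocyte and 12 of 26 lens markers were lower (2 lens markers higher), and WT replicate 2 of 2 months held 26105 CPM of hepatocyte, 85288 CPM of vitellogenin and 27138 CPM of enterocyte markers. In intestine 10 of 14 oocyte markers and 5 of 7 vitellogenins were higher with them. The lowest and highest mitochondrial shares of counts went from 9.94 and 14.5% to 20.3 and 46.6% in brain, 4.36 and 14.7% to 20.5 and 43.4% in heart, 5.76 and 7.89% to 11.98 and 17.04% in intestine, and 5.07 and 6.63% to 7.61 and 18.4% in gills. No set test was run for this comparison.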

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

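Tests chosen only after the result was seen were the median at equal depth in muscle, the comparison of clock arms in KO and the shares of recurring genes at each age, and leaving out the doubted libraries, the oocyte covariate and equal depth were added after seeing the data. In 23 of 93 tests, each of 1 measure in 1 group of 4 libraries, 1 library stood far from the other 3, where chance gives about 1 in 20. For atf3 these were KO eyes of 2 months replicate 1 (1.52 CPM), OE intestine of 2 months replicate 3 (83.2 CPM), OE muscle of 2 months replicate 1 (578 CPM), and at 4 months OE brain replicate 2 (10.1 CPM), OE gills replicate 4 (16.5 CPM), OE heart replicate 3 (54.3 CPM) and OE muscle replicate 3 (276 CPM). For total counts they were, at 2 months, KO heart replicate 2 (2355024), KO intestine replicate 4 (6716568), KO skin replicate 4 (112796069), OE eyes replicate 3 (1781821), and of WT heart replicate 2 (90542873), intestine replicate 3 (13594094), muscle replicate 3 (10419443) and skin replicate 3 (15058006), and at 4 months WT intestine replicate 4 (24408438). For vitellogenins they were OE intestine of 2 months replicate 2 (12849 CPM), WT eyes of 2 months replicate 2 (85288 CPM), KO muscle of 4 months replicate 1 (3772 CPM), WT intestine of 4 months replicate 1 (158152 CPM) and WT muscle of 4 months replicate 1 (8702 CPM). For oocyte markers they were WT muscle of 2 months replicate 4 (13817 CPM) and WT skin of 2 months replicate 4 (3639 CPM).

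The effect of a line differed between ages in 13 tests. The KO effect differed for 20 genes in muscle, 38 in brain, 199 in eyes, 444 in gills, 252 in heart, 544 in intestine and 2 in skin, and the OE effect for 8 in muscle, 4 in eyes, 640 in gills, 88 in heart, 1474 in intestine and 3258 in skin. Differences for KO were pcmtd1 3.68 and pdp1 -2.08 in muscle, nr1d2b 1.95 and nfil3-5 -3.11 in brain, nr1d1 6.31 and per1b 3.65 in eyes, nr1d1 5.09 and nfil3-5 -3.76 in gills, per1b 3.28 and ciarta 4.59 in heart, nup93 -1.73 and fen1 -3.41 in intestine and nr1d1 6.13 in skin. Differences for OE were mrto4 -2.95 and tsr1 -2.27 in muscle, nfil3-6 -2.04 and coch 2.06 in eyes, pprc1 3.04 and eif4a1a 2.48 in gills, ppp4cb 2.11 and alpl -2.13 in heart, ULK2 -5.10 and g3bp1 4.22 in intestine and pms1 -3.35 and ofd1 -2.95 in skin.

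Calls were counted in other splits of the same libraries into groups of the same sizes. Where none gave as many, the share was 1 of 35, the least possible and unadjusted over comparisons, which does not exclude chance. None did in the following (real count, highest other). Muscle: KO at 2 months (17, 1), OE at 4 months (2585, 0). Brain: KO at 2 and 4 months (54, 3 and 14, 1), WT age (868, 211). Eyes: KO at 2 and 4 months (759, 309 and 164, 8), OE at 4 months (13, 0), WT age (1414, 556). Gills: KO and OE at 2 months (666, 13 and 1742, 1), at 4 months (171, 95 and 104, 35), WT age (2700, 483). Heart: OE at 2 months (114, 6), KO and OE at 4 months (715, 3 and 405, 1), WT age (2019, 832). Intestine: KO and OE at 2 months (1059, 75 and 1237, 12), OE at 4 months (133, 13), WT age (2503, 108). Replicate numbers paired in KO intestine at 2 months and WT age of brain, where the replicate block gave 816 and 783. Age differences were drawn 60 times. For KO no draw gave as many in muscle (20, 0), eyes (199, 109), gills (444, 48), heart (252, 82) and brain (38, 18). For OE none did in muscle (8, 3), eyes (4, 1), heart (88, 41), intestine (1474, 323) and skin (3258, 2028). For OE gills (640, 1344) and KO intestine (544, 571) 2 of 60 were as large, the real one included. In OE brain at 2 months the 1 gene stood against 0, but was lost with the replicate block and in 7 of 8 omissions. With only the compared groups 0 calls were left there and in KO muscle at 2 months. The same held for the age differences of muscle and OE skin. These counts say little about chance.

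Other splits gave as many in the following (real count, splits of 35 as large, highest other). Muscle: OE at 2 months (18, 2, 1452), KO at 4 months (168, 2, 511), WT age (32, 6, 5240). Brain: OE at 4 months (6, 3, 85). Heart: KO at 2 months (370, 2, 734). Intestine: KO at 4 months (35, 3, 235). Skin: WT age (3, 2, 1285) and the KO age difference (2, 5 of 60, 618). The same held where edgeR called 0: OE eyes and OE skin at 2 months and KO skin at 4 months (35 of 35 splits, highest others 455, 2901 and 7; unadjusted p under 0.05 for 2163, 2267 and 3111 genes; DESeq2 106, 138 and 410), and the OE age difference in brain (60 of 60, 352; unadjusted 800; DESeq2 4). Splits with several times the real count, as in muscle, point to a structure of the libraries other than genotype. For gene lists no other split gave as many for KO at 2 months (117, 1, 107). Others did for OE at 2 months (87, 30, 112), KO at 4 months (85, 10, 103) and OE at 4 months (90, 8, 104). With an estimated correlation all of these counts became 0.

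The first pattern weighed was the 1715 genes lower in OE muscle of 4 months. A difference in library size stays open. Thinning every library to 1141611 counts left 373 lower calls, which by the criterion written beforehand made size the cause. But thinning also removed counts from every gene (8866 tested in place of 12542), and higher calls fell from 870 to 260. The median over 1399 of the genes, -2.5 at equal and -2.29 at full depth, cannot decide it, as thinning keeps expected shares of counts. Oocyte RNA in some libraries is a candidate explanation. With the oocyte covariate 70 lower calls were left, but 1408 without the doubted libraries. Over the 12 libraries of 2 months the genes followed the oocyte markers with r = 0.979 (permutation p 1e-05, the smallest possible). At 4 months the covariate overlaps with genotype, so an effect of OE on muscle stays open, as does sex, which the labels do not give.

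The second pattern was the genes called in KO in at least 3 tissues at one age. DNA linked to the edited site was argued against as the main source. By GRCz12tu positions 4.05% (3 of 74) lay on the chromosome of atf3, against 4.39% of all genes so tested. The ratio was 0.924 (Fisher's exact p = 1). Linkage stays open for hsf2 and znf395b, at 79 and -77 genes from atf3. Of the KO genes 7.06% (6 of 85) were also called the same way in OE. Values of the shared WT libraries stay open at both ages. At 2 months 4.23% (3 of 71) were so called, but with 0, 0 and 1 OE calls in eyes, skin and brain few could be. At 4 months 21.4% (3 of 14) were, above the bound set for excluding them. A direct effect of losing atf3 and differences in rearing stay open and were not tested.

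The third pattern was the clock genes in KO of 2 months. In 7 of 7 tissues the dawn genes were lower and the dusk genes higher, so an hour of dissection differing between KO and WT fish may account for them. An action of lost atf3 on the clock, at 2 months or both ages, stays open. At 4 months 1 of 7 tissues had that orientation by sign, but the labels give no hour of dissection, so this cannot decide.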

How the results depend on the processing

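Tests chosen only after results had been seen were 3 alternatives: leaving out the doubted libraries, the oocyte markers as a covariate and equal depth. Counts below are genes past the threshold, by edgeR unless DESeq2 is named, and are given where they moved by over 1.5 times from those of the report. The age difference is the effect at 4 months minus that at 2 months. The cause of these moves was not tested, except where fewer libraries or more genes tested follow from the alternative itself. With RLE scaling no total moved so far, though the higher or the lower genes taken apart did in some comparisons, and the largest shift of the median of all genes was -0.0942, in OE heart at 4 months.

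With DESeq2 the counts were as follows. In muscle 866 (KO at 2 months), 79 (OE at 2 months), 576 (KO at 4 months), 291 (the KO age difference), 373 (the OE age difference) and 166 (WT age). In brain 129 (KO at 2 months), 3 (OE at 2 months), 89 (KO at 4 months), 92 (OE at 4 months), 64 (the KO age difference) and 4 (the OE age difference). In eyes 106 (OE at 2 months), 358 (KO at 4 months), 88 (OE at 4 months), 324 (the KO age difference) and 31 (the OE age difference). In gills 426 (KO at 4 months) and 359 (OE at 4 months). In heart 991 (KO at 2 months), 448 (OE at 2 months), 1094 (KO at 4 months), 763 (OE at 4 months), 643 (the KO age difference) and 321 (the OE age difference). In intestine 1682 (KO at 2 months), 712 (KO at 4 months), 1021 (OE at 4 months) and 1131 (the KO age difference). In skin 346 (KO at 2 months), 138 (OE at 2 months), 410 (KO at 4 months), 3167 (OE at 4 months), 395 (the KO age difference) and 686 (WT age).

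Without the filter on low counts more genes were tested, and the counts were as follows. In muscle 9 (KO at 2 months), 86 (KO at 4 months), 1603 (OE at 4 months), 10 (the KO age difference), 0 (the OE age difference) and 11 (WT age). In brain 19 (OE at 4 months). In eyes 73 (KO at 4 months), 2 (OE at 4 months) and 113 (the KO age difference). In gills 104 (KO at 4 months). In heart 70 (OE at 2 months) and 43 (the OE age difference). In intestine 589 (KO at 2 months), 5 (KO at 4 months), 28 (OE at 4 months) and 183 (the KO age difference). In skin 6 (KO at 2 months) and 1 (OE at 4 months).

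With the replicate number as a block, as for paired samples, the counts were as follows. In muscle 4 (KO at 2 months), 6 (the KO age difference) and 1 (the OE age difference). In brain 0 (OE at 2 months). In eyes 464 (KO at 2 months), 21 (OE at 2 months) and 5 (OE at 4 months). In gills 88 (KO at 4 months) and 50 (OE at 4 months). In heart 212 (KO at 2 months), 150 (the KO age difference) and 51 (the OE age difference). In intestine 0 (KO at 4 months) and 299 (the KO age difference). In skin 2 (KO at 2 months), 325 (OE at 4 months), 886 (the OE age difference) and 25 (WT age).

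With only the compared groups in the fit, which estimates the spread from fewer libraries, the counts were as follows. In muscle 0 (KO at 2 months), 0 (OE at 2 months), 0 (KO at 4 months), 1628 (OE at 4 months), 0 (the KO age difference), 0 (the OE age difference) and 0 (WT age). In brain 104 (KO at 2 months), 0 (OE at 2 months), 1 (KO at 4 months), 0 (OE at 4 months) and 134 (WT age). In eyes 197 (KO at 2 months), 227 (OE at 4 months), 93 (the KO age difference) and 208 (WT age). In gills 1 (KO at 4 months), 26 (OE at 4 months), 226 (the KO age difference) and 1342 (WT age). In heart 22 (KO at 2 months), 1 (OE at 2 months), 433 (KO at 4 months), 687 (OE at 4 months), 50 (the KO age difference), 20 (the OE age difference) and 179 (WT age). In intestine 327 (KO at 2 months), 604 (OE at 2 months), 0 (KO at 4 months), 9 (OE at 4 months), 322 (the KO age difference) and 1179 (WT age). In skin 55 (KO at 2 months), 3512 (OE at 4 months), 8 (the KO age difference), 0 (the OE age difference) and 5 (WT age).

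Without the doubted libraries the counts were as follows. In muscle 140 (OE at 2 months), 325 (KO at 4 months), 131 (the KO age difference), 2493 (the OE age difference) and 928 (WT age). In brain 112 (KO at 2 months), 1 (the OE age difference) and 245 (WT age). In eyes 415 (KO at 2 months), 8 (OE at 2 months), 293 (KO at 4 months), 58 (OE at 4 months) and 7 (the OE age difference). In gills 68 (KO at 4 months) and 66 (OE at 4 months). In heart 191 (OE at 2 months), 1509 (KO at 4 months), 1045 (OE at 4 months) and 250 (the OE age difference). In intestine 788 (OE at 2 months) and 0 (KO at 4 months). In skin 26 (KO at 2 months), 10 (OE at 2 months), 1 (KO at 4 months), 0 (OE at 4 months), 0 (the OE age difference) and 13 (WT age). This left WT skin of 4 months with 1 library, which is assumed to vary like the other groups. The gene elovl2 in KO eyes at 2 months turned from lower to 0.17. With the oocyte markers as a covariate, run in muscle and skin, the counts were as follows. In muscle 253 (OE at 2 months), 314 (KO at 4 months), 95 (OE at 4 months), 190 (the KO age difference) and 190 (WT age). In skin 33 (KO at 2 months), 5 (OE at 2 months), 0 (OE at 4 months), 33 (the KO age difference), 0 (the OE age difference) and 17 (WT age). The covariate turned 5 genes from lower to higher estimates, zp3b in OE muscle at 4 months to 1.77 and, in OE skin at 4 months, rrm1 to 0.081, cldnd to 0.52, zar1 to 0.44 and zp3b to 0.64. With every muscle library thinned to equal depth, OE at 4 months gave 633.

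Leaving out each library in turn gave the lowest and highest counts that follow, with the genotype and replicate left out in brackets. In muscle 4 (KO 3) to 218 (WT 3) for KO at 2 months, 9 (WT 1) to 27 (WT 4) for OE at 2 months, 28 (WT 1) to 549 (WT 3) for KO at 4 months, 312 (WT 2) to 3724 (WT 3) for OE at 4 months, 0 (2 month KO 1) to 109 (2 month WT 4) for the KO age difference, 0 (2 month OE 2) to 2702 (2 month WT 4) for the OE age difference, 1 (2 month WT 1) to 1409 (2 month WT 4) for WT age. In brain 28 (KO 3) to 48 (KO 1) for KO at 2 months, 0 (OE 1) to 1 (WT 2) for OE at 2 months, 9 (KO 4) to 42 (WT 3) for KO at 4 months, 0 (OE 2) to 151 (WT 2) for OE at 4 months, 30 (2 month WT 3) to 72 (4 month WT 3) for the KO age difference, 0 (2 month OE 1) to 1 (4 month WT 2) for the OE age difference, 445 (4 month WT 3) to 1227 (4 month WT 2) for WT age. In eyes 297 (KO 3) to 1487 (WT 3) for KO at 2 months, 1 (OE 1) to 617 (WT 3) for OE at 2 months, 34 (WT 4) to 172 (KO 1) for KO at 4 months, 1 (OE 1) to 10 (WT 1) for OE at 4 months, 116 (2 month KO 1) to 234 (2 month WT 3) for the KO age difference, 1 (2 month OE 2) to 7 (2 month WT 2) for the OE age difference, 693 (4 month WT 2) to 1680 (2 month WT 3) for WT age. In gills 355 (WT 4) to 544 (WT 2) for KO at 2 months, 1053 (WT 4) to 1438 (WT 2) for OE at 2 months, 14 (WT 4) to 412 (WT 3) for KO at 4 months, 13 (OE 1) to 423 (WT 3) for OE at 4 months, 188 (4 month WT 4) to 520 (4 month KO 2) for the KO age difference, 349 (4 month WT 4) to 610 (4 month WT 3) for the OE age difference, 1564 (4 month WT 3) to 2598 (4 month WT 2) for WT age. In heart 108 (KO 3) to 648 (WT 2) for KO at 2 months, 46 (OE 2) to 191 (WT 4) for OE at 2 months, 293 (KO 4) to 577 (KO 2) for KO at 4 months, 135 (WT 2) to 477 (WT 3) for OE at 4 months, 127 (4 month KO 4) to 360 (2 month WT 4) for the KO age difference, 13 (2 month OE 1) to 250 (2 month WT 4) for the OE age difference, 1223 (4 month WT 2) to 2282 (2 month WT 4) for WT age. In intestine 476 (WT 2) to 1176 (WT 3) for KO at 2 months, 0 (KO 2) to 178 (WT 3) for KO at 4 months, 26 (OE 4) to 192 (WT 4) for OE at 4 months, 195 (4 month KO 4) to 642 (4 month WT 3) for the KO age difference. In skin 0 (KO 1) to 6 (WT 1) for KO at 2 months, 0 (OE 4) to 10 (OE 1) for OE at 2 months, 0 (KO 2) to 2 (WT 3) for KO at 4 months, 0 (OE 1) to 3284 (WT 3) for OE at 4 months, 0 (2 month KO 1) to 7 (4 month KO 2) for the KO age difference, 786 (4 month WT 4) to 4550 (4 month WT 3) for the OE age difference, 0 (2 month WT 1) to 3 (4 month WT 4) for WT age. In OE intestine at 2 months, the OE age difference and WT age of intestine, no omission moved the count by over 1.5 times. For elovl2 in eyes KO vs WT at 2 months the estimate ran from -3.12 without WT 4 to 0.15 without WT 2.

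The gene list calls, 117 for KO and 87 for OE at 2 months and 85 and 90 at 4 months, became 0 for all 4 with a correlation estimated from the data (lowest adjusted p = 0.37), and no omission of a library moved them by over 1.5 times. Of the genes named in the report, 606 gene results were past the threshold. Leaving out libraries ended 317 of these calls in at least 1 omission and reversed 1. DESeq2 ended 2 of 581, RLE scaling 10 of 606, no filter 112 of 606, the replicate block, as for paired samples, 132 of 606, the compared groups alone 212 of 548, leaving out the doubted libraries 121 of 605, the covariate 86 of 179 and equal depth 21 of 66. The size of change that could be found was limited: with 200 genes changed on simulated data in the KO comparison of 2 months, edgeR found 27 of 100 genes at 4-fold in muscle and 22 in skin, against 82 in brain and 83 in gills. At 2-fold it found 0 in muscle and skin. These tissues differ little in median depth (3065488 in muscle, 2602596 in brain), and depth was not separated from the spread between libraries.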

Other observations

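For the WT fish, a test of the hour of dissection was written before the arms were computed. If the hour differed between ages, the dawn and dusk arms would move opposite ways with one orientation in most tissues. They did so in 3 of 7. But the dawn medians ran from 0.0473 in skin to 1.12 in intestine, so a difference in hour stays open.

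The summed vitellogenin level at 4 months was low in several OE tissues. It was at most 1.2 CPM in OE muscle (30.8 to 8702 CPM in WT), at most 2.48 CPM in brain (2.82 to 554 CPM in WT), at most 0.954 CPM in eyes (9.24 to 84.9 CPM in WT) and 1.44 to 2.34 CPM in intestine (3.39 to 158152 CPM in WT), while OE heart held 18.9 to 41.2 CPM. The labels give no sex of the fish.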
